A study of Mus musculus with 32 samples.

How the data were processed

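RNA abundance was measured by RNA sequencing in 32 libraries from C57/BL6 mice. Adult males received subcutaneous implants of testosterone (25 mg) and oestrogen (2.5 mg) for 2 weeks (T+E2) or no treatment. The anterior prostate (AP), the dorsal lateral prostate (DLP) and the prostatic urethra were taken. Urogenital sinus (UGS), the embryonic tissue from which the prostate buds, was dissected at embryonic day 16.5 from embryos labelled as male. It was cultured with testosterone or without hormone, and the labels give 6 days of culture for the testosterone arm. Each of the 8 groups had 4 libraries. Libraries are named by group and by the number or letter in the submitters' sample titles.

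The deposited values are TPM (transcript abundance corrected for length and scaled to a fixed library sum) per gene in a single table for the whole series. Per the submitters' processing notes, STAR, RSEM, edgeR and FastQC were used with the mouse build mm9, without stated roles or versions. The deposited TPM table held 13780 genes, and every gene reached a mean of at least 4.998 TPM in at least 1 of the 8 groups, so it held no gene that was low in all groups. Library sums lay between 994133 and 997961 TPM. All 32 columns were matched to 1 sample each by name, and no 2 columns were identical. TPM keeps no sequencing depth, so the depth behind each value is unknown and no counting interval is given. The deposited table analysed here had TPM columns and no comparison of the authors, so the planned comparison with a deposited test did not apply. The reference annotation used here (GENCODE M21, GRCm38) is of another build than the authors', so no coordinates are printed. It served only for transcript lengths, which were matched for 13594 of 13780 genes.

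Each tissue was fitted alone (4 against 4 libraries) with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with the mean-variance trend. Genes entered with at least 1 TPM in at least 4 of the 8 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values below are from this test unless another is named. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. The difference of T+E2 effects between tissues was tested by limma over the 24 adult libraries, without blocking on the animal. The fit was tested on simulated data made from the real control means and spreads, with each gene drawn independently. It recovered 96 of 100 genes changed 2-fold in DLP, 100 of 100 in AP, 96 of 100 in urethra and 91 of 100 in UGS. It called 13, 15, 11 and 12 unchanged genes among 12888, 12305, 12765 and 13084. The simulation held no structure shared by genes or libraries, so these counts do not give the rate of false calls in the real data.

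Before the data were examined, 38 gene lists (855 entries, 731 in the table) were written from textbook knowledge. They were tested with camera (limma, preset correlation 0.01), with camera at an estimated correlation and with fry, which tests whether a list's genes move one way on balance. Genes are named in the text by a rule fixed at the same time. It took the 10 largest rises and 10 largest falls among called genes without overlap of the groups and with a mean of at least 10 TPM in the higher group, leaving out predicted and RIKEN transcripts and keeping at most 2 immunoglobulin or T cell receptor segments. It added up to 4 called members per list and 20 genes given whatever their outcome, and some of the genes it took are not reported here. Shares of TPM were compared by an exact two-sided permutation test over the 70 assignments of 8 libraries, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over 12 such tests in the adult tissues. The skeletal muscle share was tested after its values were seen.

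Alternatives were pseudocounts of 0.1 and 5, no filter or at least 5 TPM, rescaling by median-of-ratios factors, quantile normalization, rescaling without secretion, seminal vesicle and mitochondrial genes, limma arrayWeights, limma without the trend or with robust hyperparameters, an exact rank permutation test per gene, and leaving out each library. They were planned for DLP, lists and named genes and extended afterwards to the other counts. Alternatives chosen after seeing the data were a correction for transcript length (a loess curve per library), replicate blocks, and fits without libraries that held signs of other tissue or a strong length trend. Figures were drawn with matplotlib 3.10.9. The labels do not state whether equal numbers in different tissues mark 1 animal. The labels do not state that each library of a group is a separate animal or culture, so p-values measure the spread between these libraries. In UGS, letters C and H occur in both arms.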

Results

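The series compared the anterior prostate, the dorsal lateral prostate and the urethra of hormone-implanted mice, a model of benign prostatic hyperplasia, with untreated tissue, and embryonic UGS cultured with and without testosterone. Each of the 8 groups held 4 libraries. Between 12289 and 13337 genes reached 1 TPM per library. The depth of the libraries is unknown, because the deposited unit is TPM. Values are given as mean ± SD (n = 4 per group) and log2 fold changes with their standard errors.

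In DLP, the comparison asked how the transcripts of the lobe differed after T+E2. Gpx3, a secreted glutathione peroxidase, rose from 1245 ± 119.8 to 22416 ± 2444 TPM, a log2 fold change of 4.17 ± 0.12. The water channel gene Aqp8 rose from 1.63 ± 0.116 to 226 ± 32.4 TPM, and Pigr, the receptor that carries immunoglobulins across epithelium, rose from 100.3 ± 54.5 to 1142 ± 172 TPM. Probasin (Pbsn), an androgen-dependent secretory protein of the prostate, fell from 42168 ± 8175 to 13065 ± 1033 TPM. The oestrogen-induced gene Greb1 rose from 3.27 ± 0.719 to 18.0 ± 2.58 TPM. Limma called 1405 of 13108 genes, 798 higher and 607 lower, of which 163 and 133 changed at least 2-fold. The 4 values of each group did not overlap in 16.3% of genes, against 2.86% by chance.

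Other genes among the largest rises in DLP were Slc9a3, Nrn1l, Ctse, Atp13a4, Slc2a3 and Hist2h2aa2, a histone gene whose reads can be shared with a near-identical copy. Their log2 fold changes lay between 3.57 ± 0.18 for Slc2a3 and 4.71 ± 0.54 for Hist2h2aa2. Among the largest falls, Saa3, an acute phase protein gene, fell by 3.51 ± 0.64 on the log2 scale and the chemokine gene Ccl5 fell by 2.57 ± 0.28. Iigp1, Tgtp1 and Tgtp2, which encode interferon-inducible GTPases, fell from 46.4 ± 19.9 to 4.44 ± 0.627 TPM, from 13.5 ± 4.64 to 1.28 ± 0.131 TPM and from 16.0 ± 2.63 to 2.12 ± 0.700 TPM. Tgtp1 and Tgtp2 are near-identical, so their reads can be shared. C1rb, Fgl1, H2-Q10, Muc19 and the pseudogene Art2a-ps also fell, and C1rb and H2-Q10 have close relatives that can share their reads.

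Of 27 interferon response genes in DLP, 23 were lower and 0 higher (0 higher and 27 lower adjusted over the list alone). Gbp2 fell from 40.0 ± 8.98 to 8.87 ± 1.04 TPM. Camera's adjusted p for this list was 2.10e-27, or adjusted p = 0.222 with an estimated correlation. Of 16 antigen presentation genes, 13 were lower (1 higher and 14 lower adjusted over the list alone), among them Cd74, which fell from 555 ± 126 to 142 ± 11.4 TPM, and Psmb9. This list had camera adjusted p = 8.75e-17, or adjusted p = 0.189 with an estimated correlation. The interferon-induced chemokine gene Cxcl9 fell by 2.31 ± 0.21 on the log2 scale. Ptprc, which marks leukocytes, fell from 9.14 ± 3.06 to 3.79 ± 0.295 TPM beside these lists. Of 20 macrophage and dendritic cell genes, 6 were lower (0 higher and 9 lower adjusted over the list alone), among them Mertk (adjusted p = 0.586 with an estimated correlation).

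Of 14 markers of proximal luminal cells, the prostate epithelium near the urethra, 10 were higher in DLP (11 higher and 0 lower adjusted over the list alone). Psca rose from 19.2 ± 11.1 to 104 ± 48.0 TPM. The list had adjusted p = 0.373 with an estimated correlation. Of 7 urothelial genes, 4 were higher (5 higher and 0 lower adjusted over the list alone), with the uroplakin gene Upk1a rising from 149 ± 22.2 to 542 ± 75.7 TPM (adjusted p = 0.258 with an estimated correlation). Of 23 cholesterol synthesis genes, 10 were higher (18 higher and 0 lower adjusted over the list alone), among them Fdft1, the squalene synthase gene, by 1.22 ± 0.07 on the log2 scale and Insig1 (adjusted p = 0.373 with an estimated correlation). Of 36 extracellular matrix genes, 11 were higher (20 higher and 1 lower adjusted over the list alone), with the elastin gene Eln at 1.89 ± 0.27 and Col4a1 at 0.67 ± 0.13 (adjusted p = 0.586 with an estimated correlation). Prlr, the prolactin receptor gene, and Stat5a, which encodes a transcription factor downstream of it, rose by 0.58 ± 0.11 and 0.91 ± 0.11. Of 39 cell cycle genes, 6 were lower and 0 higher (0 higher and 14 lower adjusted over the list alone), and the list had adjusted p = 0.373 with an estimated correlation. Top2a fell by 0.62 ± 0.15, a call lost with arrayWeights or when any of T+E2 libraries 1, 2 and 24 or control libraries 7, 8 and 9 was left out.

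Among genes fixed in advance, Esr1 rose in DLP from 8.89 ± 1.10 to 13.5 ± 2.24 TPM, Pgr from 0.807 ± 0.316 to 2.48 ± 0.0984 TPM and Shh from 4.34 ± 0.608 to 7.62 ± 1.82 TPM. Krt5, Krt14, Trp63, Krt8, Krt10, Mki67, Acta2, Col1a1, Srd5a1, Srd5a2 and Fgf10 did not pass the test. Mki67, a proliferation marker, had 7.16 ± 1.28 TPM in control and 5.44 ± 0.270 TPM with hormone. Krt5 was called higher without T+E2 library 2 or control library 9, Mki67 lower without control library 10, and Krt10 higher without limma's trend. Esr2 was not analysed here. Skeletal muscle transcripts made up 0.339%, 0.122% and 0.375% of TPM in T+E2 libraries 18, 1 and 24 and 0.117% or less in the other 5 DLP libraries. Pvalb and Myh4, both abundant in skeletal muscle, rose by 4.09 ± 0.77 and 3.74 ± 1.02, and were the 2 higher genes of 16 skeletal muscle genes (13 higher and 0 lower adjusted over the list alone; adjusted p = 0.586 with an estimated correlation). Myh4 lost its call without any of T+E2 libraries 18, 1 and 24 and control libraries 10, 7 and 9, with pseudocount 5 and without limma's trend, and both lost it with robust hyperparameters. Without T+E2 libraries 18 and 24, 727 genes were called, and Pvalb, Myh4 and Shh lost their calls. Of 13 prostate secretion genes, 5 were lower and 1 higher (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.373 with an estimated correlation). They made up 10.8% ± 3.43 of TPM with T+E2 and 13.2% ± 2.63 in control (exact two-sided permutation p = 0.343, or adjusted p = 0.457). Sbp, on this list, ranged from 70.51 to 44601.53 TPM with T+E2 and from 52.31 to 47958.09 TPM in control. It widened the spread of the share in both groups, and the share without Sbp was not tested. Quantile normalization called 983 genes higher and 1245 lower, removal of the length trend 1113 and 1109, and arrayWeights 1013 and 1167. Rescaling without secretion, seminal vesicle and mitochondrial genes called 907 higher and 1175 lower.

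**Figure D1:**
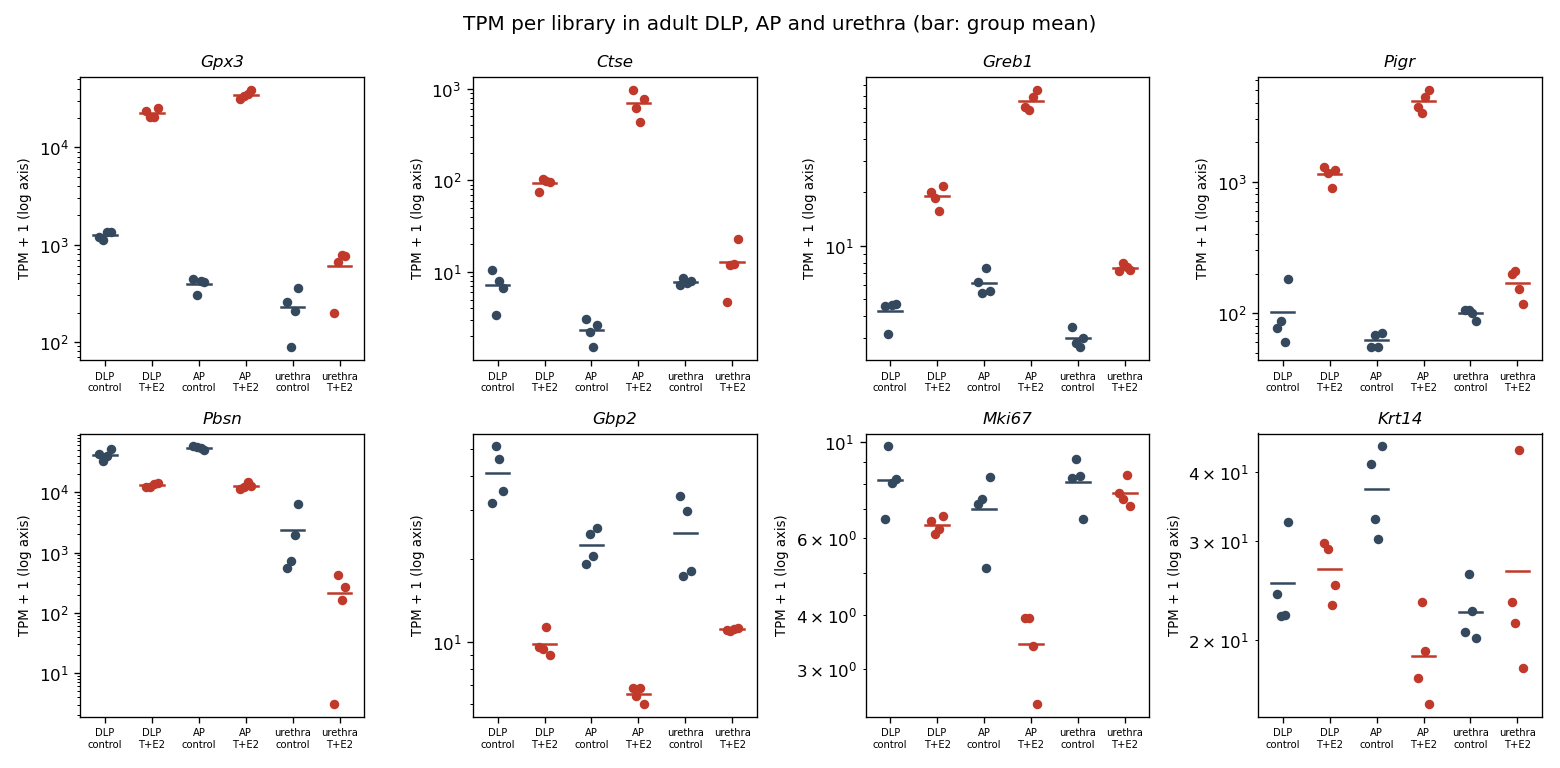
TPM + 1 on a log axis for 8 genes in the 24 adult libraries, control in dark blue and T+E2 in red, with 4 points per group and a line at the group mean. Mean Gpx3 was 1245 TPM in control and 22416 TPM with T+E2 in DLP, and 394 and 34674 TPM in AP.

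In AP, the same question was asked of the anterior lobe. Gpx3 rose from 394 ± 64.0 to 34674 ± 3160.4 TPM, and Ctse, a cathepsin gene, from 1.34 ± 0.660 to 701 ± 228 TPM. Msmb, which encodes a secreted prostate protein, rose from 45.2 ± 29.7 to 2630.5 ± 1879 TPM and the beta-defensin gene Defb50 from 1650.5 ± 309.7 to 36312 ± 7414 TPM. Pbsn fell from 54271 ± 3426 to 12791 ± 1436 TPM. Limma called 4323 of 12525 genes, 2706 higher and 1617 lower, of which 484 and 289 changed at least 2-fold. The groups did not overlap in 34.4% of genes, against 2.86% by chance. Median-of-ratios rescaling called 2196 genes higher and 2321 lower, quantile normalization 1993 and 2625, and removal of the length trend 2411 and 2417. Rescaling without secretion, seminal vesicle and mitochondrial genes called 2184 higher and 2006 lower.

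Aqp8, Slc2a3, Slc9a3, Nrn1l, Ncald, Pigr and Spinkl were the other large rises in AP, with log2 fold changes between 6.03 ± 0.14 for Pigr and 8.09 ± 0.43 for Aqp8. The largest falls were Olfm4, which fell from 27.5 ± 1.78 to 0.158 ± 0.125 TPM, and Serpinb1a, Pnliprp1, Steap1, Gpha2, Sec14l2, Chac1, Degs2, Gsdma3 and Ang. The prostate secretion transcript 9530002B09Rik fell by 4.09 ± 0.11. Of 12 prostate secretion genes, 6 were lower and 5 higher (5 higher and 7 lower adjusted over the list alone; adjusted p = 0.589 with an estimated correlation), and camera's call of this list was lost without T+E2 library 3 or control library 7 and with median-of-ratios rescaling or quantile normalization. They made up 15.6% ± 1.16 of TPM in control and 9.27% ± 1.19 with T+E2 (exact two-sided permutation p = 0.0286, the smallest the design allows, or adjusted p = 0.114).

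Of 36 cell cycle genes in AP, 30 were lower and 1 higher (2 higher and 31 lower adjusted over the list alone). Top2a fell from 18.3 ± 3.12 to 2.97 ± 0.705 TPM and Mki67 from 6.00 ± 1.35 to 2.43 ± 0.675 TPM, and the list had adjusted p = 0.469 with an estimated correlation. Of 39 ribosomal protein genes, 28 were lower (0 higher and 32 lower adjusted over the list alone), Rpl12 by 0.73 ± 0.11 (adjusted p = 0.469 with an estimated correlation). Of 26 interferon response genes, 21 were lower (0 higher and 23 lower adjusted over the list alone), and Gbp2 fell from 21.5 ± 3.17 to 5.52 ± 0.404 TPM (adjusted p = 0.469 with an estimated correlation). Of 16 antigen presentation genes, 12 were lower and 1 higher (1 higher and 13 lower adjusted over the list alone), with H2-Ab1 falling from 166 ± 29.8 to 42.1 ± 13.4 TPM (adjusted p = 0.469 with an estimated correlation). Of 19 macrophage and dendritic cell genes, 11 were lower (0 higher and 12 lower adjusted over the list alone), among them Mertk (adjusted p = 0.469 with an estimated correlation). Beside these lists Ptprc fell from 5.07 ± 0.724 to 2.87 ± 0.794 TPM, a call lost without the 3 libraries rich in seminal vesicle transcripts. Of 14 general luminal genes, 8 were lower and 1 higher (1 higher and 10 lower adjusted over the list alone), with Krt8 falling from 402 ± 10.6 to 291 ± 14.6 TPM and Hoxb13 from 399 ± 23.9 to 297 ± 36.2 TPM (adjusted p = 0.469 with an estimated correlation). Of 16 smooth muscle genes, 7 were lower (0 higher and 8 lower adjusted over the list alone), among them Cnn1 by 0.67 ± 0.15 on the log2 scale (adjusted p = 0.589 with an estimated correlation).

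Of 12 proximal luminal genes, 6 were higher in AP (7 higher and 0 lower adjusted over the list alone), and Psca rose from 12.1 ± 2.56 to 48.1 ± 15.2 TPM (adjusted p = 0.469 with an estimated correlation). Of 6 urothelial genes, 4 were higher (4 higher and 0 lower adjusted over the list alone), and Upk1a rose from 20.8 ± 1.37 to 633 ± 184 TPM (adjusted p = 0.469 with an estimated correlation). Of 16 oestrogen response genes, 8 were higher and 1 lower (8 higher and 1 lower adjusted over the list alone), with Greb1 rising from 5.17 ± 0.946 to 64.6 ± 8.05 TPM and Prlr from 73.2 ± 6.20 to 171 ± 40.5 TPM (adjusted p = 0.469 with an estimated correlation). Of 23 cholesterol synthesis genes, 15 were higher (15 higher and 0 lower adjusted over the list alone), Fdft1 by 3.19 ± 0.12 and Insig1 by 0.60 ± 0.08 (adjusted p = 0.589 with an estimated correlation). Stat5a rose by 1.58 ± 0.10 and the collagen gene Col6a1 by 0.50 ± 0.06. Esr1 rose from 15.1 ± 3.55 to 31.7 ± 9.40 TPM, and Pgr and Shh also rose. Srd5a1 rose by 0.32 ± 0.08, a call lost without the 3 libraries rich in seminal vesicle transcripts. Trp63 passed at adjusted p = 0.0197, and lost its call with median-of-ratios rescaling, quantile normalization or the length trend removed, and without T+E2 library 3 or control library 6. The basal keratin gene Krt14 fell from 36.2 ± 6.66 to 17.7 ± 3.46 TPM. Krt5, Krt10, Acta2, Col1a1, Srd5a2 and Fgf10 did not pass. Acta2 was called without T+E2 library 18 and Col1a1 without T+E2 library 17 or control library 6. Seminal vesicle transcripts made up 9.98% and 7.27% of TPM in T+E2 libraries 17 and 18 and 5.43% in control library 9, against 0.261% or less in the other 5 AP libraries. Of 8 seminal vesicle genes, 3 were higher (3 higher and 0 lower adjusted over the list alone), and camera did not call the list. Without these 3 libraries, 3809 genes were called, Srd5a2 among them.

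T+E2 changes of the lobes overlapped. Of 12473 genes tested in both, 605 were higher in both lobes (163.4 expected of independent lists) and 483 lower in both (76.98 expected), while 7 were higher in DLP and lower in AP and 8 the reverse. The log2 fold changes correlated across genes with Pearson r = 0.711 and Spearman rho = 0.628, and genes are not independent replicates. Some library numbers occur in both lobes, so the lobes may come in part from the same mice. The effect differed between AP and DLP for 1408 of 13469 genes by limma's test of the difference, 967 with the more positive value in AP and 441 with the more negative. Median-of-ratios rescaling gave 835 and 821 and quantile normalization 702 and 610. Ctse differed by 4.41, Slc2a3 by 3.26, Upk1a by 2.96 and Fdft1 by 1.97 on the log2 scale, more positive in AP. Top2a differed by -1.66 and Krt14 by -1.09, more negative in AP. The effect differed from that in urethra for 3290 genes in AP (2339 more positive in AP, or 1673 of 3496 with median-of-ratios rescaling) and for 490 genes in DLP (332 more positive in DLP, or 408 of 922 with quantile normalization).

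In urethra, the comparison asked the same of the prostatic urethra. Greb1 rose from 2.00 ± 0.349 to 6.50 ± 0.357 TPM. Ltf, Lcn2 and Defb6, which encode the defence proteins lactoferrin, lipocalin and a beta-defensin, rose by 2.24 ± 0.37, 1.04 ± 0.12 and 2.49 ± 0.37. Pip, which encodes a secreted protein, fell from 7226 ± 1209 to 3359 ± 216 TPM. Limma called 47 of 12985 genes, 26 higher and 21 lower, of which 15 and 4 changed at least 2-fold. The groups did not overlap in 8.10% of genes, against 2.86% by chance. Other rises were Abcb5, Tceal7, Ptgds, Prss32, Rasd1, Wisp2 and Ccl9, and other falls Creb3l1, Fxyd2, Sp100, Susd2, Cxcl17, Itih5, Itga1, Tbc1d16 and Fdps. Greb1, Tceal7, Prss32, Ccl9 and Cxcl17 stayed called when any 1 library was left out, and each of the other genes named here lost its call without T+E2 library 2. Lcn2, Pip, Sp100 and Itga1 lost it without that library alone, and the others also without 1 or more of T+E2 libraries 3 and 4 and control libraries 7, 8 and 10. Ltf, Ptgds, Itih5 and Tbc1d16 were not called without the filter on low values or without limma's trend, nor were Defb6, Ltf and Ptgds with robust hyperparameters. The count was 7 without T+E2 library 2, 15 without 3, 29 without 4 and 140 without 1, and 18 without control library 10, 11 without 7, 22 without 8 and 174 without 6.

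Of 27 interferon response genes in urethra, 0 passed by limma over all genes (0 higher and 18 lower adjusted over the list alone), and all 27 had negative log2 fold changes with a median of -0.49 (camera adjusted p = 9.16e-11, or adjusted p = 0.51 with an estimated correlation). Cholesterol synthesis genes had a median of -0.34, and 1 of 23 was lower (0 higher and 18 lower adjusted over the list alone; adjusted p = 0.51 with an estimated correlation). The difference between DLP and urethra was called for 18 of these genes (camera adjusted p = 3.25e-20, or adjusted p = 0.104 with an estimated correlation). Of 32 unfolded protein response genes, 2 were lower (0 higher and 21 lower adjusted over the list alone), Creb3l1 by 1.15 ± 0.14 (adjusted p = 0.51 with an estimated correlation). Esr1, Pbsn, Krt5, Krt14, Trp63, Krt8, Krt10, Mki67, Acta2, Col1a1, Ptprc, Srd5a1, Srd5a2, Shh and Fgf10 did not pass, and Pgr was too low to be tested. Ptprc and Srd5a2 were called lower with arrayWeights. Of 14 proximal luminal genes, 1 was higher, namely Ltf (5 higher and 0 lower adjusted over the list alone; adjusted p = 0.51 with an estimated correlation). Skeletal muscle transcripts made up 9.47% ± 1.18 of TPM with T+E2 and 7.20% ± 0.700 in control, and each T+E2 library (8.00% or more) lay above each control library (7.83% or less; exact two-sided permutation p = 0.0286, the smallest the design allows, or adjusted p = 0.114). Of 17 skeletal muscle genes, 2 were higher and 15 had positive log2 fold changes (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.40e-11, or adjusted p = 0.51 with an estimated correlation). Across genes, deviations from the gene mean correlated with transcript length at Spearman rho = -0.256 and -0.356 in T+E2 libraries 2 and 4, 0.0451 and 0.0292 in T+E2 libraries 1 and 3, and 0.0302 to 0.236 in control. Beside this, none of 39 ribosomal protein genes passed by limma (0 higher and 0 lower adjusted over the list alone) and all 39 had positive log2 fold changes with a median of 0.10 (camera adjusted p = 3.26e-07, or adjusted p = 0.652 with an estimated correlation), a call lost with quantile normalization or the length trend removed. None of 42 oxidative phosphorylation genes passed (0 higher and 0 lower adjusted over the list alone), and 41 had positive values (camera adjusted p = 1.40e-11, or adjusted p = 0.652 with an estimated correlation). Prostate secretion genes made up 1.17% and 3.24% in control libraries 7 and 8, against 0.226% or less in the other 6. Without these 2 libraries, 6 genes were called, and of the genes named here Greb1, Creb3l1 and Fxyd2 kept their calls.

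**Figure D2:**
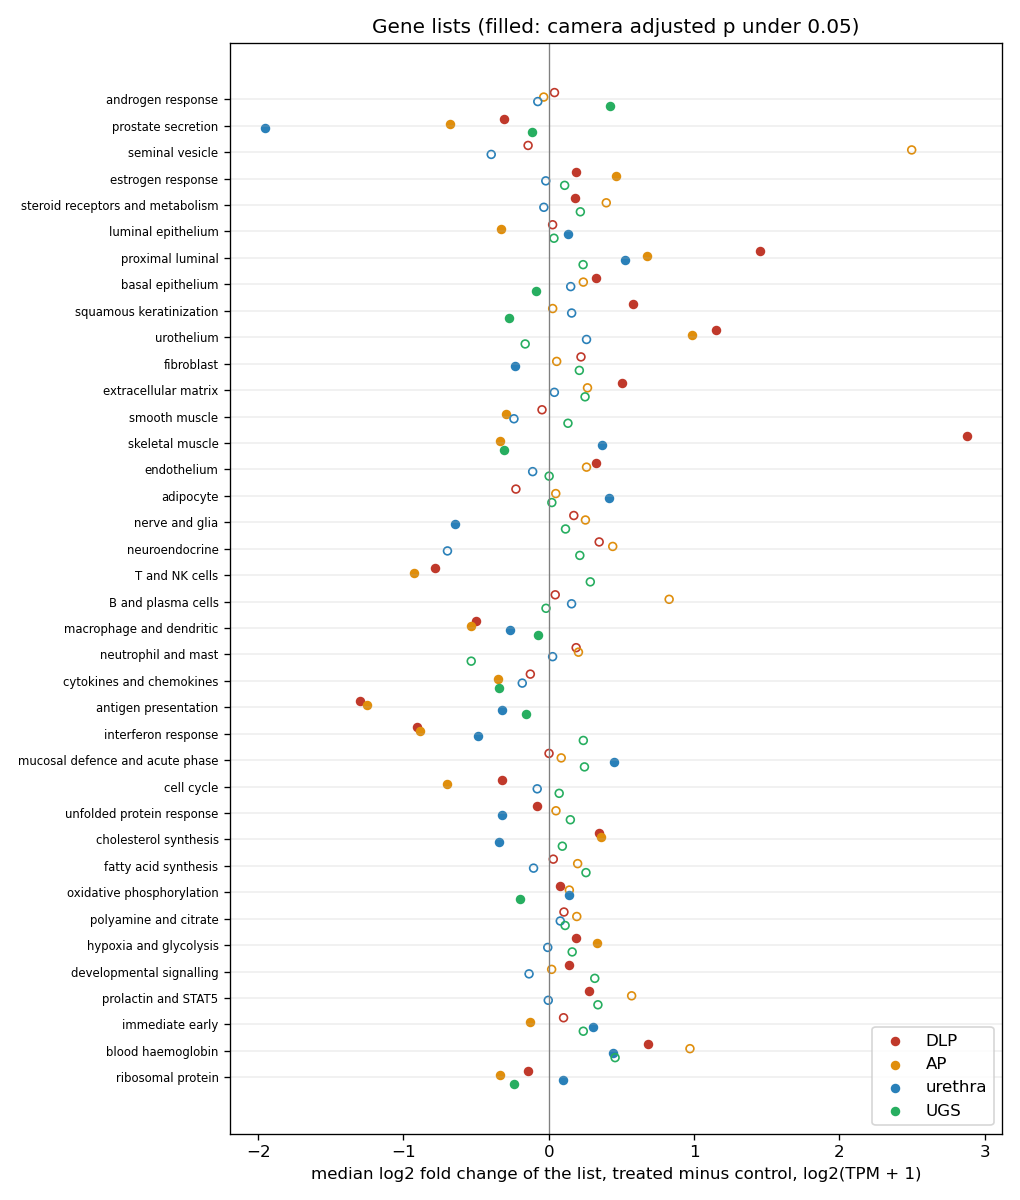
Median log2 fold change of each gene list (x axis, treated minus control on the log2(TPM + 1) scale) in the 4 comparisons, with filled points for camera adjusted p under 0.05 at the preset correlation. Interferon response lay at -0.91 in DLP, -0.89 in AP and -0.49 in urethra.

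In cultured UGS, the comparison asked which transcripts differed with testosterone. Srd5a2, the gene of an enzyme that converts testosterone to dihydrotestosterone, rose from 6.89 ± 1.90 to 63.4 ± 18.7 TPM. The steroid-induced gene Fkbp5 rose from 16.6 ± 2.88 to 78.9 ± 10.7 TPM and Zbtb16, which encodes a zinc finger transcription factor, from 0.198 ± 0.142 to 7.72 ± 4.06 TPM. Fgf10, a growth factor gene of prostate budding, rose from 11.7 ± 1.09 to 34.8 ± 8.03 TPM, and the Wnt inhibitor gene Wif1 from 4.70 ± 0.545 to 14.2 ± 1.72 TPM. Crabp1, which encodes a retinoic acid binding protein, fell from 409 ± 51.1 to 134 ± 26.2 TPM, and Dkk2, which encodes a regulator of Wnt signalling, from 115 ± 11.5 to 58.6 ± 11.0 TPM. Limma called 230 of 13304 genes, 190 higher and 40 lower, of which 99 and 15 changed at least 2-fold. The groups did not overlap in 10.8% of genes, against 2.86% by chance.

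Other large rises in UGS were Nt5e, Adamdec1, Mkx, Aldh1a1, Fam189a1, Col24a1, Epha3, Irs4 and Gdpd2, with log2 fold changes between 2.22 ± 0.12 for Gdpd2 and 3.17 ± 0.18 for Nt5e. Of 29 androgen response genes, 7 were higher and 0 lower (10 higher and 2 lower adjusted over the list alone), among them Zbtb16 and Hpgd (adjusted p = 0.92 with an estimated correlation). In the adult tissues with T+E2 this list did not move one way, with 2 of 30 genes higher and 3 lower in DLP and 7 of 29 higher and 8 lower in AP. In urethra 0 of 30 were called. Camera did not call the list in DLP (camera adjusted p = 0.839), AP (0.129) or urethra (0.86). Sult1e1, which encodes an oestrogen sulphotransferase, and Col12a1 rose by 3.07 ± 0.35 and 1.81 ± 0.33. Sfrp2 rose by 0.79 ± 0.10, a call lost with median-of-ratios rescaling. The other falls included Adamts18, Dpt, S100a4, Pnliprp1, Dsc3, Vstm2b, Lgals7, Cntnap4 and Lum. Of 15 basal epithelial genes, 3 were lower (0 higher and 3 lower adjusted over the list alone), namely Krt14, which fell from 146 ± 38.4 to 79.6 ± 10.1 TPM, Dsc3 and Lgals7 (adjusted p = 0.92 with an estimated correlation). Epha3, Col12a1, Dpt, S100a4, Dsc3, Lgals7, Cntnap4, Lum and Krt14 lost their calls when 1 or more single libraries were left out, each of them without no-hormone library C except Lgals7, which lost its call without testosterone library B, C or G or no-hormone library H. All of these but Dpt and Lgals7 also lost their calls without others of testosterone libraries B, C and G and no-hormone libraries A, D and H. S100a4, Dsc3 and Krt14 were not called without the filter on low values or without limma's trend, nor was Cntnap4 without the filter or Epha3 without the trend. Esr1, Pgr, Greb1, Krt5, Trp63, Krt8, Krt10, Mki67, Acta2, Col1a1, Ptprc, Srd5a1 and Shh did not pass. Without testosterone library H, Greb1, Mki67 and Shh were called. Pgr was called lower with quantile normalization or the length trend removed, and Pbsn was too low to be tested.

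Values in UGS moved with transcript length. Across genes, the log2 fold change correlated with transcript length at Spearman rho = 0.667, against 0.00726 in DLP, 0.0213 in AP and -0.294 in urethra, and genes are not independent replicates. Its median was -0.21 for transcripts under 1 kb and 0.47 for those over 5 kb. Of 39 ribosomal protein genes, none passed (limma, 0 higher and 0 lower adjusted over the list alone), and all 39 had negative log2 fold changes with a median of -0.24 (camera adjusted p = 1.66e-18, or adjusted p = 0.639 with an estimated correlation), a call lost with quantile normalization. Of 42 oxidative phosphorylation genes, none passed (limma, 0 higher and 0 lower adjusted over the list alone), and 35 had negative values with a median of -0.20 (camera adjusted p = 1.97e-13, or adjusted p = 0.639 with an estimated correlation). With the length trend removed per library, 379 genes were called, 233 higher and 146 lower, and 186 of the 230 were among them, while S100a4 and Lgals7 were not. The median log2 fold change of all genes was 0.17, and 0.0015 with median-of-ratios rescaling, which called 170 genes higher and 90 lower. Quantile normalization called 166 higher and 133 lower. The count was 4558 without testosterone library H, 106 without B, 134 without C and 138 without G, and 96 without no-hormone library C and 133 without H. All 8 UGS libraries, labelled as from male embryos, held Xist, expressed from the inactive X chromosome, at 157 to 792 TPM and the Y-linked Ddx3y at 0.08 TPM or less. The 24 adult libraries held Xist at 0.85 TPM or less and Ddx3y at 28.3 to 63.3 TPM. The values of all 8 UGS libraries argue against their label as male. These sex-linked genes were chosen after their values were seen.

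**Figure D3:**
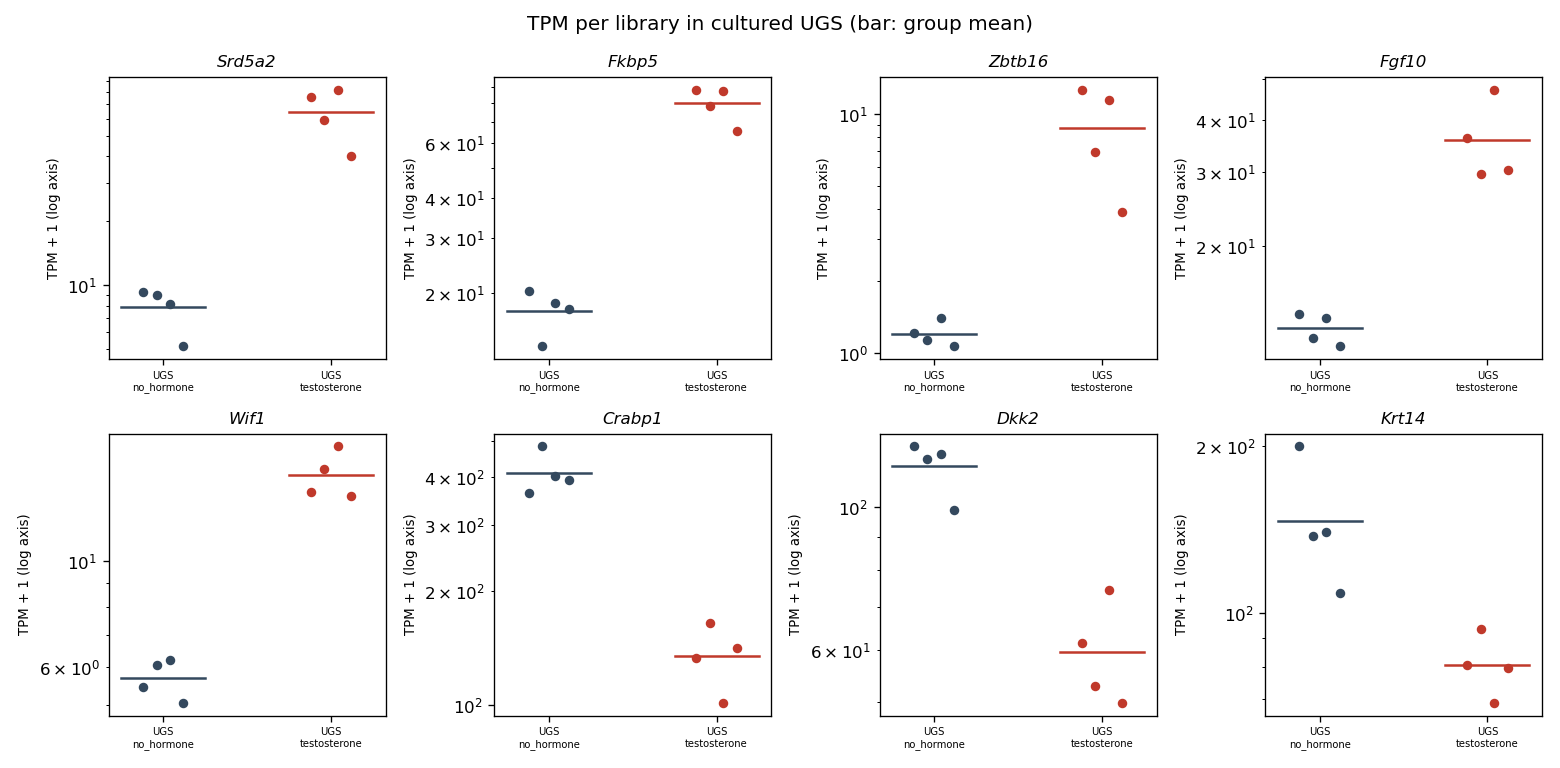
TPM + 1 on a log axis for 8 genes in the 8 UGS libraries, no hormone in dark blue and testosterone in red, with a line at the group mean. The 4 testosterone values lie above the 4 others for Srd5a2, Fkbp5, Zbtb16, Fgf10 and Wif1, and below them for Crabp1, Dkk2 and Krt14.

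Over all lists, camera with the preset correlation called 23 of 38 in DLP, 17 of 38 in AP, 17 of 37 in urethra and 10 of 37 in UGS. With an estimated correlation it called 0, with lowest adjusted p of 0.189, 0.469, 0.51 and 0.367, and fry called 11, 24, 2 and 1. Fry called interferon response lower in DLP (fry adjusted p = 0.000781) and AP (0.00299), but not in urethra (0.101). Antigen presentation was also called lower by fry in DLP (0.000543) and AP (0.00717). Cell cycle genes were called lower by fry in AP (0.00711) but not in DLP (0.0537), and androgen response was not called in UGS (0.116).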

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

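The counts over other divisions of the libraries were planned before their results were seen, and the tests of tissue carry-over, seminal vesicle material, leukocytes, control libraries, control animals and transcript length were chosen after the result was seen.

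Among 394 groups of 4 values tested for a library far from the others, 17 held one (4.31%), and chance gives about 1 in 20. In DLP, control library 8 stood apart with Pvalb at 10.12 TPM, Myh4 at 13.6 TPM, a skeletal muscle share of 0.1166% and Tgtp2 at 19.87 TPM. Control library 7 had Greb1 at 2.19 TPM and library 10 Krt10 at 1.59 TPM. In AP, control library 9 had a seminal vesicle share of 5.434% and Ang at 106.5 TPM. Control library 8 had Stat5a at 264.7 TPM and Esr1 at 20.43 TPM, and T+E2 library 17 had Srd5a1 at 7.21 TPM. In urethra, Prss32 stood at 7.66 TPM in T+E2 library 1 and at 2.66 TPM in control library 8, which also had Srd5a2 at 9.25 TPM. In UGS, testosterone library H had Lgals7 at 30.04 TPM, no-hormone library A had Krt10 at 21.92 TPM and testosterone library C had a prostate secretion share of 0.02162%.

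The T+E2 effect differed between tissues by limma's test of the difference for 1408 genes in AP against DLP, 3290 in AP against urethra and 490 in DLP against urethra. AP minus DLP, the log2 difference was 4.409 for Ctse, 3.259 for Slc2a3, 2.21 for Slc9a3, 2.305 for Nrn1l, 2.301 for Gpx3, 2.415 for Pigr, 1.252 for Greb1, 2.963 for Upk1a and 1.966 for Fdft1. It was -0.4386 for Krt8, -1.087 for Krt14, -1.661 for Top2a and -0.7023 for Mki67. AP minus urethra, it was 2.085 for Greb1, -0.6314 for Krt8, -1.155 for Krt14, 1.078 for Esr1, -0.9515 for Mki67 and 1.502 for Srd5a2. DLP minus urethra, it was 0.8338 for Greb1.

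The real division gave the largest count of 35, the most extreme rank possible, for changed genes in DLP (1405, highest other 32), AP (4323, highest other 1) and urethra (47, highest other 25). It also did so for 2-fold changes in DLP (296, highest other 26) and AP (773, highest other 1). With several counts ranked this way, the rank alone cannot exclude chance. In DLP and AP the counts lay far above every other division, which argues against chance there. Such a margin does not by itself mark the treatment, because in UGS a division other than the real one gave 4452 genes. In urethra the margin was small and the count fell to 7 without T+E2 library 2, so chance cannot be excluded. Nor can it be excluded for 2-fold changes in urethra (19, 2 of 35 as large, highest other 25) or in UGS for changed genes (230, 2 of 35, highest other 4452) and 2-fold changes (114, 2 of 35, highest other 404). The division with 4452 genes set testosterone B, C and G with no-hormone A against the rest, which points to a structure of the samples. These 4 libraries had the highest correlations with transcript length in UGS. For lists called by camera, chance cannot be excluded in DLP (23, 2 of 35, highest other 24), AP (17, 3 of 35, highest other 18), urethra (17, 4 of 35, highest other 24) or UGS (10, 24 of 35, highest other 22). Over 100 regroupings within tissues, the real labels gave the largest count for AP against urethra (3290, 1 of 100, highest other 2739) and DLP against urethra (490, 1 of 100, highest other 131). These regroupings also break up the T+E2 effect within each tissue. The rank therefore argues against labels without any effect, and cannot decide whether the effects of 2 tissues differ. For AP against DLP chance cannot be excluded (1408, 10 of 100, highest other 3807). Regroupings that come close to exchanging the labels of 1 lobe turn an effect common to both lobes into a difference.

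Msmb, Defb50 and Spinkl, all present in DLP, rose in AP. Without the 3 libraries that held over 1% seminal vesicle transcripts, the smallest of their log2 fold changes was 4.713 ± 0.178 for Defb50, which argues against seminal vesicle material as the cause. As DLP tissue carried over, Defb50 would need at least 71.4% and Spinkl at least 18% of T+E2 libraries 18, 2 and 3. DLP markers were 8 genes with at least 20 TPM in every DLP library and at most 5% of their lowest DLP value in AP controls. In these libraries 7 of the 8 stayed below the share each gene needed. This argues against carry-over for Defb50 and Spinkl there and leaves a response of AP to the hormones as a hypothesis. The markers did not move as 1 set (0% for Crisp1 and 924% for 5430419D17Rik in library 3) and gauge DLP tissue loosely. Akr1b7, Crisp1, Ptgs2 and Serpina1f stood at 38.3% to 74.4% in library 17 and at 3.45% or less in libraries 18, 2 and 3. They may therefore follow a tissue other than DLP. Without them, Abo, BB123696 and Wfdc3 still stayed below the share that Defb50 and Spinkl needed in libraries 18, 2 and 3, and 5430419D17Rik lay above it. Msmb would need at least 9.08% in libraries 2 and 3, where 4 of the 8 markers stayed below. Svs2 allowed at most 0.203% there, but AP control library 9 held Svs2 at 26855.6 TPM and Msmb at 30.68 TPM. Svs2, on the seminal vesicle list, therefore cannot gauge DLP tissue, and carry-over and a response of AP cannot be told apart for Msmb there. A first bound, that Sbp and Spink3 allow under 1%, was missed at 2.19%, and the division by library was made after library 17 missed the bound of 6 markers. In library 17 Defb50 would need 60.4%, Spinkl 17.2% and Msmb 6.16% with 5, 3 and 1 of the 8 markers below, while Sbp and Spink3, which ranged from 52.31 to 47958 TPM and from 14.58 to 19993 TPM over the DLP libraries and so bound it loosely, allowed at most 1.71%, and in library 18 Msmb would need 5.52% with 5 below, so for these carry-over and a response of AP cannot be told apart, because the markers point both ways.

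Interferon response genes fell in DLP and AP. Leaving out any 1 library left medians of -0.8667 or further below 0 in DLP and -0.7328 or further below 0 in AP, and each control library's list mean lay above each T+E2 library's, which argues against 1 control library as the cause. Ptprc had a log2 fold change of -1.03 in DLP and -0.6657 in AP beside list medians of -0.91 and -0.89. Leukocyte lists did not move one way. In DLP and AP the medians were -0.50 and -0.53 for macrophage and dendritic cells and -0.78 and -0.93 for T and NK cells. They were 0.19 and 0.20 for neutrophils and mast cells and 0.04 and 0.83 for B and plasma cells. Fewer leukocytes and lower expression per cell cannot be told apart in bulk tissue. The list mean differed by -0.5001 in urethra (exact two-sided permutation p = 0.0286, the smallest the design allows). Each urethra control library (3.366 or more on the log2 scale) lay above each T+E2 library (3.241 or less). The outcome set for a state of the control animals was thus met, and a hormone effect in urethra would give it too. A state of the control animals and the hormone effect cannot be told apart, because all control libraries come from untreated animals.

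Testosterone calls in UGS came with a transcript length trend. With the trend removed, 186 of 230 genes were still called, which argues against the trend as the whole cause of the calls. The percent of calls that were higher moved from 82.6 to 61.48, between the bounds set for the test. Length and a testosterone effect on long transcripts therefore cannot be told apart as sources of the excess of higher calls.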

How the results depend on the processing

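Fits without libraries holding other tissue or a length trend, removal of the length trend, replicate blocks, and the alternatives for AP, urethra, UGS and the differences between tissues were chosen after the data were seen. No result called both as reported and under an alternative changed direction between them. Under pseudocount 5, 2-fold changes numbered 168 in DLP, 475 in AP, 6 in urethra and 56 in UGS, against 296, 773, 19 and 114, because a larger pseudocount shrinks the changes of low genes. Quantile normalization called 2228 genes in DLP, 73 in urethra and 922 for DLP against urethra, and median-of-ratios rescaling 76 in urethra. With arrayWeights, 2180 genes were called in DLP, 2335 in urethra (127 at least 2-fold) and 7616 in UGS (753 at least 2-fold), and 2675, 4947 and 1545 for AP against DLP, AP against urethra and DLP against urethra. With the length trend removed, 2222 were called in DLP, 71 in urethra, 379 in UGS and 741 for DLP against urethra. The cause of these shifts was not tested. The exact rank permutation test called 0 genes in DLP, AP, urethra and UGS, where its smallest p of 0.0286 was reached by 2140, 4314, 1052 and 1440 genes and the lowest adjusted p were 0.175, 0.083, 0.353 and 0.255. Limma's unadjusted p was under 0.05 for 3264, 5629, 1908 and 4277 genes.

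With fewer samples, 727 genes were called in DLP without the 2 libraries with most muscle transcripts. Without the 2 urethra libraries with most secretion transcripts, 6 genes were called in urethra, and 6 changed at least 2-fold. Without testosterone B and G, 62 genes were called in UGS and 54 changed at least 2-fold. With any 1 library left out, counts ranged from 950 to 1355 in DLP (2-fold 265 to 373), 3418 to 4443 in AP (718 to 806), 7 to 174 in urethra (4 without T+E2 library 2 to 83 without control library 6) and 96 to 4558 in UGS (71 without no-hormone C to 628 without testosterone H). They ranged from 1084 to 1657 for AP against DLP, 2698 to 3569 for AP against urethra and 372 to 596 for DLP against urethra. The difference in secretion share ranged from -3.679 to -1.164 points in DLP and from -6.88 to -5.958 in AP. Over the other settings, 64 values of named genes lost their call, 17 gained one and 29 of uncalled genes changed sign, against 2122 that kept their side. Over lists, these were 131, 27, 53 and 1727. For lists, the side is camera's direction, and an uncalled list that changed side was counted as such even where it gained a call. With 1 library left out, they were 116, 9, 16 and 1339 for named genes and 47, 47, 52 and 1054 for lists. The unknown depth limits what can be said of low genes.

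The letters C and H occur in both UGS arms, and their same-letter correlations of 0.0624 for C and 0.627 for H do not show that they pair the samples. With the letter as a replicate block, 2884 genes were called in UGS and 297 changed at least 2-fold, from 4 libraries and 1 residual degree of freedom with 14.25 prior ones. The same 4 libraries called 82 genes without a block and 524 with the letters crossed, so a block called more genes than none under either pairing, and more with the letters as given. Over 15 pairs of same-numbered adult libraries, deviations from the group mean had a median correlation of 0.0806, and 6 exceeded 0.1. Over 81 pairs with different numbers the median was -0.0194, and 18 exceeded 0.1. Not every library correlated best with its own number. These values do not settle whether the numbers mark 1 animal, and the main fits did not use them to pair libraries. With the animal number as a replicate block, 1515, 3508 and 571 genes differed for AP against DLP, AP against urethra and DLP against urethra.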

Other observations

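The lists were fixed before the data were examined, and the sex-linked genes were chosen after their values were seen. Of 24 hypoxia and glycolysis genes in AP, 13 were higher and 1 lower (13 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0257, or adjusted p = 0.589 with an estimated correlation), a call lost without control library 8 or without the 3 libraries rich in seminal vesicle transcripts. Of 14 endothelial genes in DLP, 2 were higher (7 higher and 0 lower adjusted over the list alone; adjusted p = 0.586 with an estimated correlation). Of 20 T and NK cell genes on the list, only Thy1 and Lck were tested in the lobes. Both were lower in both lobes, and Thy1 also marks fibroblasts. Their median log2 fold change was -0.78 in DLP (adjusted p = 0.258 with an estimated correlation) and -0.93 in AP (adjusted p = 0.469 with an estimated correlation), where camera's call was lost with median-of-ratios rescaling, quantile normalization or the length trend removed. Genes of the seminal vesicle list made up 15.3% to 26.8% of TPM with T+E2 and 17.3% to 23.9% in control in DLP, and none of 9 passed by limma (0 higher and 2 lower adjusted over the list alone).

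Transcripts of the sex chromosomes differed between the UGS libraries, labelled as from male embryos, and the adult males. Over 8 UGS libraries, Eif2s3y, Kdm5d and Uty reached at most 0.09, 0.03 and 0.24 TPM. Over 24 adult libraries, they lay at 31.0 to 126, 9.08 to 17.6 and 11.0 to 25.4 TPM. Like Xist and Ddx3y, these genes argue against the male label of the UGS libraries.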
